A study of Homo sapiens with 2 samples.

How the data were processed

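Stromal cells of healthy human subcutaneous and omental adipose tissue were profiled by droplet single-cell RNA sequencing with a 10x Genomics 3′ kit. Per the labels' protocols, thawed tissue was minced and digested with collagenase, the floating adipocyte fraction was discarded, and the remaining cells were sorted on CD45, a surface protein of blood-derived cells. Per the labels, each of the 2 libraries pooled tissue of the same 5 donors. The series holds 1 subcutaneous and 1 omental library, and no cell in the deposited cell tables carries its donor.

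The submitters' processing notes name Cell Ranger 3.1, STAR, Seurat 4.0.1 and the GRCh38 genome; the gene annotation behind the counts is not given in the sources used here. The authors deposited gene by cell matrices that their names call normalized. Every deposited value was tested and is a whole number, and the values of a cell add up to the total UMI count that the authors' cell table gives for it in 7347 of 7349 fibroblasts and in all 18783 cells of the larger matrix. The matrices were therefore used as raw counts of unique molecular identifiers (UMIs), with no normalization by the authors assumed. In the remaining 2 fibroblasts the table's total is damaged text, and the total was taken from the matrix. The matrix of all cells has 24426 genes, and that of the fibroblasts 25617, of which 24426 are shared and hold identical counts in the shared cells. The percent of UMIs from mitochondrial genes per cell, deposited by the authors in the cell table, reached at most 25.0%, and the smallest total was 500 UMIs. All 18783 cells carry the authors' call of a single cell, so no further doublet removal was run. The set of fibroblasts and its 4 clusters, numbered 0, 1, 3 and 5, were taken from the authors' cell table. No cell was removed here.

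Before the data were examined, the planned comparison was a model across donors with the donor as a block. Because the cells carry no donor, there is 1 sample per depot, and the fallback fixed at the same time was used: both values, their ratio and its counting error, with no test and no p-value between depots. UMIs were summed per gene over the cells of a library, or of a cluster or class within it, and divided by the total and scaled to 1000000 counts per profile (CPM). Intervals of a CPM are exact 95% Poisson intervals, those of a ratio exact 95% conditional binomial intervals, and those of a share exact 95% binomial (Clopper-Pearson) intervals. All of them cover counting error only, and not the spread between cells, between people or between preparations. Ratios are of plain CPM, and log2 folds are log2 of the omental over the subcutaneous value after adding 5 CPM to each, which understates the difference of genes with low counts. Genes with a mean of at least 10 CPM over both libraries were measured, leaving out XIST and Y-linked genes, and a gene counted as higher in a depot at a log2 fold of at least 1. A gene without any UMI in a library was set against a floor of 3 counts per library, which is also the limit given for a share of 0 and is 0.176 CPM in the subcutaneous and 0.0995 CPM in the omental fibroblasts. For such a gene "at least" gives the ratio to this floor, and the 95% interval of the ratio begins lower.

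The 25 gene lists of pathways and fibroblast types and the 15 lists of cell type markers were written before the data were examined. A list is described by the median log2 fold of its measured members and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins; the percentile describes these 2 libraries and is not a test. The rule for named genes was also fixed in advance. It takes the 12 largest log2 folds in each direction among genes with at least 50 CPM in the higher library, leaving out mitochondrial, ribosomal protein, immunoglobulin and haemoglobin genes and identifiers without a gene name. It adds NR3C1, HSD11B1, FKBP5, TSC22D3, ZBTB16, KLF9 and PER1, up to 4 members of each list with the largest folds among those at least 2-fold apart (the 2 most expressed members where none was), and 3 genes per direction in each cluster or class. In a cell class, these 3 were taken among genes whose counting interval excluded a ratio of 1, a condition added after the data were seen because some classes have few cells. The interval takes UMIs as independent, so this condition does not guard against counts that come from very few cells. The genes of the glucocorticoid lists were also compared between clusters and classes within each library, each against the mean of the others.

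The cell table of all cells gives no cell types. The cells were therefore clustered on 2000 variable genes after scaling each cell to 10000 counts and taking logarithms, with 30 principal components, a shared-neighbour graph of 15 neighbours and the Leiden method at resolution 1, which gave 23 clusters. A cluster was called like a cell type when at least 3 markers of that type were detected and it led the other types among the cluster's 10 top genes; a cluster of very low UMI counts or with tied types stayed unnamed. The authors' fibroblasts kept the authors' name, and other cells in clusters made of them were held apart. A different set of names could give other shares. Clusters or classes needed at least 20 cells in both libraries for a comparison between depots.

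Gene positions and overlaps come from the GENCODE 29 annotation of GRCh38, in which 30 of 31 genes looked up were found by symbol. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The fibroblast comparison was tested on simulated counts for 7260 genes. All 50 of 50 genes at a simulated 2.5-fold difference were placed at 2-fold or more in the right direction. So were 50 of 50 at 4-fold and 50 of 50 at 8-fold, but 0 of 50 at 1.5-fold and 0 of 7060 unchanged genes. Adding 5 CPM shrinks the fold of low genes, so a 2.5-fold difference near the filter on mean CPM would fall below 2-fold. The rate at 2.5-fold therefore does not extend to genes near that filter. The ratio's interval covered the true value in 95.5% of unchanged genes, and 4.5% of 200 lists without a shift fell beyond the 2.5 or 97.5 percentile. Both rates describe simulated counts only, and not the spread between cells, between people or between preparations.

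Alternatives fixed before the data were examined changed the pseudocount, the filter on low values, the smallest number of cells, the scaling, the averaging over cells, the number of cells, the cells holding mesothelial markers, the list members and the denominator of shares. The comparisons with synovial or arthritic tissue that the series title touches on were not analysed here.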

Results

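Adipose tissue from beneath the skin (subcutaneous) and from the omentum, the fatty apron of the abdominal cavity, was compared by single-cell RNA sequencing of its stromal cells. Each depot had 1 library, and each library pooled the same 5 donors. The subcutaneous library held 3103 cells and 24127454 UMIs, with a median of 6963 UMIs and 1965 genes per cell. The omental library held 15680 cells and 88347980 UMIs, with a median of 4694.5 UMIs and 1557 genes per cell. The median share of mitochondrial UMIs per cell was 6.83% and 7.99%, in this order. The authors' fibroblasts numbered 1866 in the subcutaneous library, with 17040135 UMIs and a median of 8739.5 per cell, and 5483 in the omental library, with 30159380 UMIs and a median of 5105. With 1 library per depot no difference has a replicate check, and every interval below is a 95% interval of counting error. Values are given with the subcutaneous library first.

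The first comparison asks how fibroblasts of both depots differ. Fibroblasts of the omental library carried far more of the growth factor pleiotrophin (PTN), of the insulin-like growth factor binding protein IGFBP2 and of the matrix protein SPARCL1. They also carried more of the transcription factors NR2F1 and TCF21, which mark mesenchyme of internal organs. Fibroblasts of the subcutaneous library carried more of the fatty acid transporter CD36, of the noncoding RNA CRNDE and of the collagen-associated protein CTHRC1. Of 25617 genes, 7258 were measured, 349 of them at least 2-fold higher in the omental and 162 at least 2-fold higher in the subcutaneous library. The counting interval of the ratio excluded 1 for all 349 and all 162. The median log2 fold of the measured genes was 0.05, and 93.0% of them lay within 2-fold. By the mean of log values per cell, the median gene lay at −0.13, and 46.4% of the genes at least 2-fold apart were higher in the omental library, against 68.3% by summed counts.

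**Figure D1:**
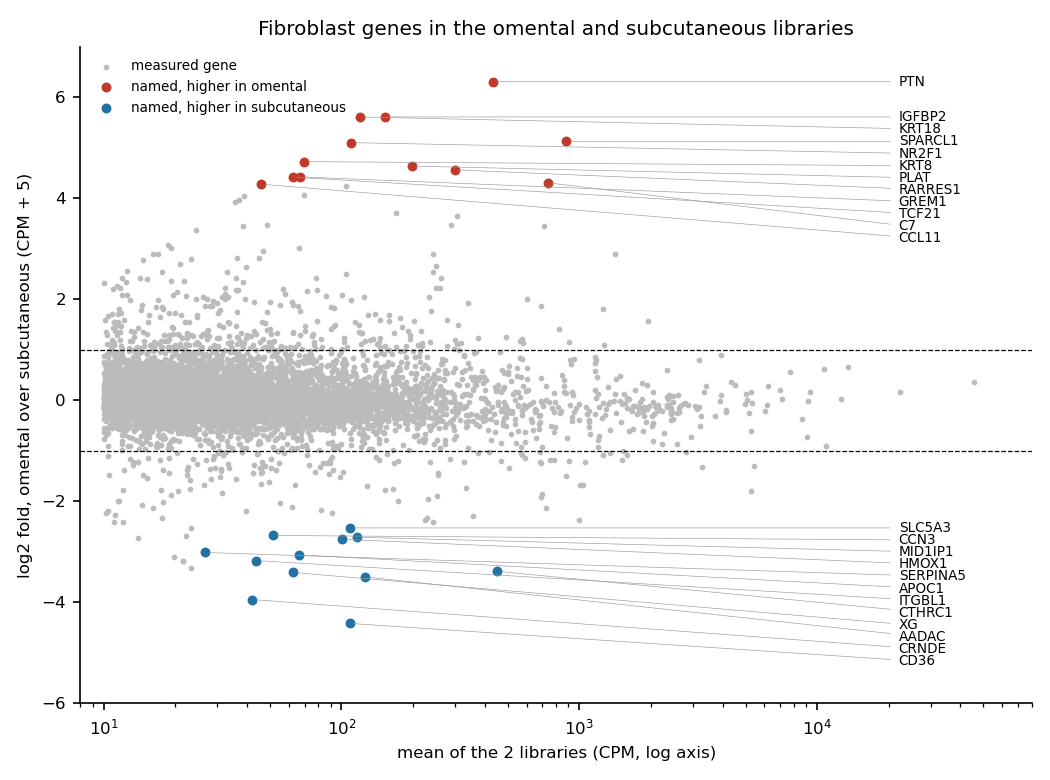
Each dot is 1 of 7258 measured fibroblast genes, placed by its mean CPM over both libraries (log axis) and by its log2 fold, omental over subcutaneous, after adding 5 CPM; dashed lines mark log2 folds of 1 and −1. Coloured dots are the 12 named genes per direction, with PTN at 6.31 as the highest and KRT18 at 5.61.

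Among genes higher in the omental library, PTN (chromosome 7, 137227341 to 137343865, GRCh38) stood at 5.87 CPM (4.77 to 7.14) against 859 CPM (848 to 869), a ratio of 146-fold (120.3 to 179.9). IGFBP2 (chromosome 2, 216632828 to 216664436) stood at 1.29 against 303 CPM, 235-fold (155 to 375) higher, and SPARCL1 (chromosome 4, 87473335 to 87531061) at 44.4 against 1722 CPM, 38.8-fold (36.1 to 41.8) higher. Among regulators, NR2F1 was 148-fold (100.4 to 229) higher at 1.47 against 218 CPM, and TCF21 124-fold (77.3 to 213) higher at 0.998 against 124 CPM. GREM1, a secreted antagonist of bone morphogenetic proteins, was 94.4-fold (63.3 to 147) higher at 1.41 against 133 CPM. RARRES1, a retinoid-induced gene, stood at 19.8 against 582 CPM, a ratio of 29.4-fold (26.4 to 32.9). The plasminogen activator PLAT stood at 10.6 against 385 CPM, 36.2-fold (31.3 to 42.2) higher, and complement C7 at 66.5 against 1414 CPM, 21.2-fold (20.03 to 22.6) higher. The eotaxin gene CCL11, whose product attracts eosinophils, had no UMI in subcutaneous fibroblasts and 92.3 CPM in omental ones. It was at least 524-fold higher against the floor, with a counting interval that begins at 426. The keratins KRT18 (0 against 239.8 CPM, at least 1362-fold higher against the floor, interval from 1107) and KRT8 (0.411 against 139 CPM, 337-fold, 164 to 839) overlap on opposite strands and have many pseudogenes, so their separate values are uncertain. In omental T, NK and B-type cells, which should lack these transcripts, KRT18 reached a level only 3.64-fold and KRT8 only 5.23-fold below that of fibroblasts. Without the 190 omental fibroblasts that fell into mesothelial-like clusters, KRT18 stood at 39.2 CPM and KRT8 at 24.4 CPM. Both then lay below their levels in those lymphoid cells, 65.9 and 26.5 CPM.

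Among genes higher in the subcutaneous library, CD36 (chromosome 7, 80369575 to 80679277) stood at 211 CPM (205 to 218) against 5.14 CPM (4.36 to 6.02), a ratio of 41.1-fold (35.01 to 48.6). CRNDE (chromosome 16, 54845189 to 54929189), a long noncoding RNA, stood at 83.7 against 0.763 CPM, 109.7-fold (72.8 to 174) higher. CTHRC1, a secreted protein of matrix-producing fibroblasts, stood at 831 against 75.0 CPM, 11.1-fold (10.6 to 11.6) higher. The lipid and haem enzymes AADAC (236 against 16.4 CPM, 14.4-fold, 13.1 to 15.9) and HMOX1 (179 against 22.4 CPM, 8.01-fold, 7.36 to 8.71) were higher as well, as was MID1IP1, a regulator of fatty acid synthesis, at 205 against 27.1 CPM and 7.56-fold (7.00 to 8.17). The cell surface gene XG stood at 118 against 6.63 CPM, 17.8-fold (15.4 to 20.7) higher, and the matricellular gene CCN3 at 93.0 against 10.3 CPM, 8.99-fold (7.95 to 10.2) higher. The remaining 4 share exon bases with a neighbouring gene on the same strand, so their counts are uncertain. They were ITGBL1 at 82.7 against 4.74 CPM (17.5-fold, 14.7 to 20.9), the apolipoprotein gene APOC1 at 123 against 10.3 CPM (11.9-fold, 10.5 to 13.4), the protease inhibitor gene SERPINA5 at 51.3 against 1.99 CPM (25.8-fold, 19.9 to 34.1) and the inositol transporter gene SLC5A3 at 188 against 28.6 CPM (6.59-fold, 6.11 to 7.11). In lymphoid cells of the subcutaneous library SLC5A3 lay 2.93-fold below its fibroblast level. Apart from SLC5A3, KRT18 and KRT8, the level in lymphoid cells lay at least 9.52-fold below that in fibroblasts for each of the 12 genes per direction given so far.

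Developmental transcription factors separated the depots in both directions. Homeobox genes of the IRX and HOXC groups, TBX15 and TWIST1, which pattern trunk and limb tissue, were higher in the subcutaneous library. The visceral regulators NR2F1, TCF21, WT1 and the retinoic acid synthase ALDH1A2 were higher in the omental library. All 6 measured of 20 subcutaneous patterning factors were at least 2-fold higher in subcutaneous fibroblasts, with a list median log2 fold of −2.75 (percentile 0). IRX2 stood at 46.5 against 0.166 CPM, 281-fold (119.8 to 867) higher, IRX1 at 42.8 against 0.298 CPM, 143-fold (75.1 to 315) higher, and HOXC9 at 39.4 against 0.199 CPM, 198-fold (90.5 to 541) higher. TBX15 stood at 21.9 against 0.0995 CPM, where 3 UMIs in omental fibroblasts put the ratio at 221-fold (74.9 to 1075). All 11 measured of 20 visceral factors lay above 0, 7 of them by at least 2-fold, with a median of 1.83 (percentile 100). WT1 stood at 0.0587 against 74.5 CPM, with 1 UMI in subcutaneous fibroblasts and a ratio between 228 and 50167. ALDH1A2 stood at 0.939 against 22.6 CPM, 24.1-fold (14.7 to 42.4) higher. The list of retinoid metabolism, which makes and binds vitamin A derivatives, had a median of 1.64 (percentile 100), with 8 of 12 measured genes of 18 at least 2-fold higher in the omental library. Beside RARRES1 and ALDH1A2 it held ALDH1A1 at 64.3 against 434 CPM, 6.76-fold (6.35 to 7.19) higher.

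Genes that NF-κB induces were mostly higher in subcutaneous fibroblasts, and cytokine genes were split. The former included the adhesion molecule ICAM1, the NF-κB inhibitor TNFAIP3, the hyaluronan-binding protein TNFAIP6 and the neutrophil-attracting chemokine CXCL2. The list of genes induced by NF-κB, the transcription factor of acute inflammation, had a median log2 fold of −0.49 over 17 of 19 genes (percentile 0), with 14 members below 0 and 3 above, 6 of them at least 2-fold lower in the omental library and none higher by that much. ICAM1 stood at 239 against 66.8 CPM, 3.58-fold (3.39 to 3.78) higher in the subcutaneous library, CXCL2 at 1301 against 457 CPM, 2.85-fold (2.79 to 2.91), TNFAIP3 at 124 against 49.8 CPM, 2.48-fold (2.32 to 2.66), and TNFAIP6 at 652 against 282 CPM, 2.31-fold (2.24 to 2.37). The cytokine and chemokine list had a median of −0.61 over 16 of 26 genes (percentile 0), or −0.62 with CCL11 at the floor. Its members were split, 8 above and 8 below 0, and all 8 of the latter but only 3 of the former were at least 2-fold apart, so the median lies in a gap between both groups. CCL20 stood at 32.9 against 2.52 CPM, 13.0-fold (10.2 to 16.8) higher in the subcutaneous library, CXCL10 at 21.3 against 1.66 CPM, 12.8-fold (9.54 to 17.6), and CXCL3 at 369.5 against 91.6 CPM, 4.03-fold (3.86 to 4.22). IL6, CXCL8 and CCL2 were chosen after their values were seen. IL6 stood at 463 against 195 CPM and CXCL8 at 518 against 151 CPM, whereas the monocyte chemokine CCL2 was near equal at 1468 against 1608 CPM. Complement genes had a median of 0.21 over 15 of 17 genes (percentile 97.2), inside the central 95% of random lists, with 12 above and 3 below 0 and 3 at least 2-fold apart. C7 and the protease CFI were higher in the omental library, CFI at 3.46 against 136 CPM (39.3-fold, 30.4 to 51.7).

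Several genes of lipid handling and fat cell commitment were higher in subcutaneous fibroblasts. CD36 imports fatty acids, FABP4 carries them inside the cell, CIDEC enlarges lipid droplets, and APOE and APOC1 coat lipoproteins. The adipogenesis and lipid handling list had a median log2 fold of −0.40 over 18 of 27 genes (percentile 0), with 11 members below 0 and 7 above, and 5 at least 2-fold higher in the subcutaneous library. APOE stood at 1666 against 319 CPM, 5.22-fold (5.10 to 5.34), FABP4 at 402 against 104 CPM, 3.86-fold (3.70 to 4.03), and CIDEC at 23.6 against 0.431 CPM, 54.9-fold (31.7 to 104). The list of committed preadipocytes, which shares CD36, APOE and FABP4 with it, had a median of −0.76 over 16 of 22 genes (percentile 0), with 7 lower and none higher in the omental library by 2-fold. The list of DPP4- and PI16-positive progenitors, thought to feed the fat lineage, had a median of 0.10 over 17 of 20 genes (percentile 78.8) and a mean of −0.09, and its median turned to −0.16 by the mean of log values per cell. Its members parted, with PRG4 at 138 against 26.7 CPM and DPP4 at 29.7 against 7.86 CPM but SFRP4 at 104 against 277 CPM and PI16 at 73.9 against 167 CPM. The list of CXCL12- and F3-positive fibroblasts near vessels had a median of 0.80 over 15 of 18 genes (percentile 100), with 6 higher and 1 lower in the omental library. Beside C7, it held the flavin monooxygenase FMO2 at 67.3 against 419 CPM (6.23-fold, 5.86 to 6.62), the lipid transporter ABCA8 at 85.3 against 415 CPM (4.87-fold, 4.61 to 5.14) and, on the subcutaneous side, GDF10 at 68.4 against 11.1 CPM (6.16-fold, 5.45 to 6.98). Genes of the synovial lining had a median of 0.46 over 9 of 15 genes (percentile 99.3) with a mean of −0.05. This median fell to 0.08 by the mean of log values per cell, 0.16 without cells holding 3 mesothelial markers and 0.18 without cluster 5. The list's largest folds were those of PRG4, TSPAN15 at 34.7 against 6.499 CPM and HBEGF at 6.10 against 20.2 CPM.

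Several secreted regulators were higher in the omental library, among them the WNT regulators RSPO3, SFRP1 and SFRP2, the thrombospondin THBS1 and the growth factor binding protein IGFBP7. Others, such as the WNT antagonist DKK3 and CTHRC1, were higher in the subcutaneous library. The WNT list had a median log2 fold of 0.95 over 10 of 21 genes (percentile 100), 7 above and 3 below 0, with RSPO3 at 19.8 against 320.2 CPM (16.2-fold, 14.5 to 18.1), SFRP1 at 43.4 against 534 CPM (12.3-fold, 11.4 to 13.3), SFRP2 at 116 against 1311 CPM (11.3-fold, 10.8 to 11.9) and, higher in the subcutaneous library, DKK3 at 51.9 against 11.1 CPM (4.69-fold, 4.13 to 5.33). The insulin-like growth factor list had a median of 0.73 over 11 of 14 genes (percentile 100.0), with 5 higher and none lower in the omental library by 2-fold. They included IGFBP2, PAPPA at 8.22 against 56.6 CPM (6.88-fold, 5.79 to 8.24), IGF2 at 9.98 against 63.2 CPM (6.33-fold, 5.41 to 7.45) and IGFBP7 at 974 against 2921 CPM (3.00-fold, 2.95 to 3.05). The TGF-β and myofibroblast list had a median of 0.40 over 19 of 21 genes (percentile 99.8), 12 above and 7 below 0, which turned to −0.0370 when the authors' clusters were weighted equally. THBS1 at 40.7 against 572 CPM (14.04-fold, 13.0 to 15.2), COMP at 4.34 against 34.8 CPM (8.01-fold, 6.32 to 10.3) and COL8A1 at 6.75 against 42.2 CPM (6.26-fold, 5.17 to 7.64) were higher in the omental library, opposite to CTHRC1.

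The matrix itself differed by component. Fibrillar collagen COL3A1 was higher in the subcutaneous library, and the small proteoglycans ASPN and PRELP, the elastic fibre protein FBLN5 and the laminins LAMB1 and LAMA2 were higher in the omental library. The collagen and core matrix list had a median of 0.18 over all 29 genes (percentile 99.3), with 15 above and 14 below 0, and its sign changed to −0.15 with clusters weighted equally. ASPN stood at 53.3 against 432 CPM (8.09-fold, 7.57 to 8.67), PRELP at 109.7 against 278 CPM (2.54-fold, 2.41 to 2.67), FBLN5 at 222 against 529 CPM (2.38-fold, 2.30 to 2.47) and COL3A1 at 1476 against 630.4 CPM (2.34-fold, 2.30 to 2.39 higher in the subcutaneous library). The basement membrane list had a median of 0.30 over 12 of 15 genes (percentile 96.3), with LAMB1 at 27.6 against 181 CPM (6.57-fold, 5.97 to 7.23) and LAMA2 at 108 against 230.4 CPM (2.13-fold, 2.02 to 2.24). Matrix remodelling enzymes had a median of −0.16 over 22 of 27 genes (percentile 7.07) and a mean of 0.23, and their median turned to 0.40 with at least 50 CPM required. Beside PLAT, the metalloproteinases ADAMTS1 at 106 against 372 CPM (3.53-fold, 3.36 to 3.71) and MMP23B at 14.8 against 52.6 CPM (3.56-fold, 3.11 to 4.08) and the urokinase receptor PLAUR at 119 against 257 CPM (2.16-fold, 2.06 to 2.27) were higher in the omental library.

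Glucocorticoid signalling is the subject named in the series title. Cortisol acts through the receptor NR3C1, the enzyme HSD11B1 makes active cortisol inside the cell, and FKBP5, TSC22D3, ZBTB16, KLF9 and PER1 are among the genes the receptor induces. All 7 were higher in omental fibroblasts, each by less than 2-fold. FKBP5 (chromosome 6, 35573585 to 35728583) stood at 84.6 CPM (80.3 to 89.1) against 161 CPM (157 to 166), a ratio of 1.91-fold (1.80 to 2.02). KLF9 (chromosome 9, 70384597 to 70414624) stood at 394 against 574 CPM, 1.46-fold (1.42 to 1.49997), ZBTB16 (chromosome 11, 114059593 to 114250676) at 215 against 297 CPM, 1.38-fold (1.33 to 1.43), and TSC22D3 (chromosome X, 107713221 to 107777342) at 522 against 636 CPM, 1.22-fold (1.19 to 1.25). PER1 (chromosome 17, 8140472 to 8156506), which shares exon bases with AC129492.3, stood at 49.2 against 66.0 CPM, 1.34-fold (1.24 to 1.46). NR3C1 (chromosome 5, 143277931 to 143435512) stood at 87.1 against 107 CPM, 1.22-fold (1.15 to 1.30), and HSD11B1 (chromosome 1, 209686178 to 209734950) at 22.7 against 31.2 CPM, 1.38-fold (1.22 to 1.56).

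The glucocorticoid response list had a median log2 fold of 0.44 over 34 of 40 genes (percentile 100), with 7 higher and 2 lower in the omental library by at least 2-fold. Its largest log2 folds were those of TXNIP, an inhibitor of glucose uptake, at 238 against 969 CPM (4.07-fold, 3.94 to 4.21), glutamine synthetase GLUL at 294 against 1092 CPM (3.71-fold, 3.60 to 3.82) and the growth inhibitor DDIT4 at 25.5 against 106 CPM (4.16-fold, 3.76 to 4.60). ANGPTL4, an inhibitor of lipoprotein lipase, went the other way at 377 against 133 CPM (2.83-fold, 2.72 to 2.94). The other member at least 2-fold lower in the omental library was NFKBIA at 2157 against 1024 CPM (2.11-fold, 2.08 to 2.14), which NF-κB also induces and which the NF-κB list holds too. The metallothioneins, whose near-identical copies make each count uncertain, went both ways, with MT2A at 11327 against 6859 CPM and MT1A at 663 against 1158 CPM, both chosen after their values were seen. The list of the receptor, its partners and cortisol metabolism had a median of 0.33 over 14 of 19 genes (percentile 98.8) and a mean of −0.08, and its median fell to 0.17 by the mean of log values per cell or with clusters weighted equally. The steroid reductases AKR1C2 at 154 against 28.8 CPM (5.32-fold, 4.93 to 5.75) and AKR1C3 at 149 against 48.7 CPM (3.05-fold, 2.86 to 3.25), similar copies with uncertain counts, were its only members at least 2-fold apart, both higher in the subcutaneous library.

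Stress and immune lists come next. Chaperones that refold proteins, such as HSPH1 and HSPA1A, were higher in omental fibroblasts, as were the antigen presentation gene CD74 and its HLA class II partners. The heat shock list had a median of 0.68 over all 15 genes (percentile 100), with HSPH1 at 46.7 against 134 CPM (2.86-fold, 2.65 to 3.09), HSPA1A at 446 against 1204 CPM, its near copy HSPA1B at 196 against 399 CPM and DNAJB4 at 22.8 against 64.6 CPM. Immediate early genes had a median of 0.12 over 26 of 27 genes (percentile 97.52), which turned to −0.0929 by the mean of log values per cell, with the nuclear receptors NR4A3 at 12.9 against 41.9 CPM and NR4A1 at 346 against 785 CPM furthest apart. The list of major histocompatibility genes had a median of 0.20 over 15 of 18 genes (percentile 93.6), with CD74 at 22.9 against 120.4 CPM, HLA-DRB1 at 17.6 against 82.6 CPM, HLA-DPA1 at 13.97 against 59.0 CPM and HLA-DRA at 19.7 against 77.6 CPM. In lymphoid cells CD74 stood at 815 and 842 CPM, so free RNA of immune cells was not separated from its level in fibroblasts, and HLA genes share reads with close copies. Interferon response genes had a median of 0.07 over 16 of 23 genes (percentile 51.8), −0.13 by the mean of log values per cell, with BST2 at 87.5 against 379 CPM and IRF1 at 505 against 242 CPM. Hypoxia and glycolysis genes had a median of −0.31 over 17 of 21 genes (percentile 0.370), led by PFKFB3 at 72.1 against 19.4 CPM and CA12 at 20.7 against 6.00 CPM. Only PCNA at 23.7 against 20.8 CPM and MCM3 at 9.39 against 10.8 CPM of 16 cell cycle genes were measured, with a median of −0.01.

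Markers of other cell types in the fibroblasts were led by those of mesothelium, the epithelium that lines the abdominal cavity. The mesothelial list had a median log2 fold of 3.93 over 9 of 15 genes (percentile 100), or 8.66 with its 4 members without subcutaneous UMIs at the floor, and its members included KRT18, KRT8, WT1 and KRT19 at 0 against 78.0 CPM (at least 443-fold higher). Without the 190 omental fibroblasts in mesothelial-like clusters KRT19 stood at 16.1 CPM, near its 15.5 CPM in omental lymphoid cells. The pericyte and smooth muscle list had a median of 1.37 over 5 of 14 genes (percentile 100.0), with CNN1 at 0.293 against 23.5 CPM, RGS5 at 0.704 against 21.3 CPM and TAGLN at 118 against 314 CPM. Fibroblast markers had a median of 0.33 over all 12 genes (percentile 99.4), with DPT at 558 against 1962 CPM and FBLN1 at 803 against 1736 CPM higher in the omental library, and COL3A1 and COL1A1 at 2091 against 919 CPM higher in the subcutaneous library. Macrophage and monocyte markers had a median of −0.48 over 4 of 15 genes (percentile 0.710), which turned to 0.19 with no filter on low values, with VCAN at 280.1 against 67.1 CPM and LYZ at 2.35 against 18.6 CPM. The NK cell list had a median of 0.17 over NCAM1 at 1.06 against 27.3 CPM and FGFBP2 at 26.5 against 2.45 CPM. Lists with 1 measured member were endothelial (EMCN, −2.26), lymphatic endothelial (PDPN, 1.05), T cell (TRAC, −0.99), B and plasma cell (IGKC, 3.38, at 48.97 CPM in omental fibroblasts against 19143 CPM in omental lymphoid cells), Schwann and neural (NCAM1, 2.42) and mature adipocyte (CIDEC, −2.40), and the dendritic, mast cell, neutrophil and erythroid and platelet lists had 0.

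The next comparison asks whether the depots differ within each of the authors' 4 fibroblast clusters. Pleiotrophin was higher in the omental library, and CD36 in the subcutaneous library, within clusters led by very different genes. The leading genes were DEPP1, FMO2, ECRG4, EDNRB and COL15A1 in cluster 0, and COMP, HMOX1, CXCL3, CXCL8 and PTX3 in cluster 1. They were PRG4, CD24, FBN1, KCNAB1 and MFAP5 in cluster 3, and HP, KRT8, KRT18, KRT19 and CLDN1 in cluster 5. Cluster 0 held 943 subcutaneous and 2667 omental fibroblasts, 50.5% (48.2 to 52.8) against 48.6% (47.3 to 49.97). Cluster 1 held 739 and 1970, 39.6% (37.4 to 41.9) against 35.9% (34.7 to 37.2), and cluster 3 held 164 and 402, 8.79% (7.54 to 10.2) against 7.33% (6.66 to 8.05). Cluster 5 held 20 and 444, 1.07% (0.656 to 1.65) against 8.10% (7.39 to 8.85), but its leading keratins themselves differ between the depots, so no direction is read from its size. All cells were sorted on CD45 before pooling. The omental cells of cluster 5 fell mostly into clusters 1 (mesothelial-like, 173 cells) and 13 (256 cells) of the clustering of all cells, and its 20 subcutaneous cells into cluster 2, so this comparison sets different cells side by side. That clustering also parted the depots in clusters 0, 1 and 3, of which 940, 736 and 151 subcutaneous but only 3, 6 and 2 omental cells fell into its cluster 2.

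Within cluster 0, 318 of 7402 measured genes were at least 2-fold higher in the omental and 195 in the subcutaneous library. PTN stood at 7.15 against 1092 CPM (153-fold, 118 to 202), NR2F1 at 1.76 against 269.7 CPM (153-fold, 91.4 to 281) and GREM1 at 2.01 against 199.8 CPM (99.5-fold, 61.2 to 174). On the subcutaneous side AADAC stood at 177 against 1.64 CPM (108-fold, 71.3 to 174), CD36 at 262 against 6.84 CPM (38.2-fold, 31.0 to 47.6) and XG at 142 against 2.16 CPM (66.0-fold, 45.7 to 99.01). Within cluster 1, with 384 and 179 of 6883 genes, PTN stood at 4.89 against 837 CPM (171-fold, 124 to 243), IGFBP2 at 1.32 against 404 CPM (306-fold, 166 to 638) and SPARCL1 at 34.9 against 1947 CPM (55.8-fold, 49.4 to 63.2), and on the subcutaneous side AADAC at 309.6 against 8.19 CPM (37.8-fold, 30.8 to 46.9), CD36 at 181 against 4.92 CPM (36.9-fold, 28.3 to 48.9) and APOC1 at 132 against 4.92 CPM (26.8-fold, 20.5 to 35.7). Within cluster 3, with 467 and 206 of 7594 genes, PTN had no subcutaneous UMI and 203 CPM in the omental library. It was at least 86.3-fold higher against the floor, with an interval that begins at 69.9. PTGDS stood there at 19.6 against 477 CPM (24.4-fold, 16.4 to 37.8) and PLAT at 24.3 against 548 CPM (22.6-fold, 15.8 to 33.3), and on the subcutaneous side AADAC at 188 against 3.58 CPM (52.5-fold, 26.2 to 123), APOE at 215 against 5.37 CPM (40.0-fold, 22.5 to 78.3) and CTHRC1 at 844 against 43.4 CPM (19.4-fold, 15.8 to 24.2). Within cluster 5, mesothelial markers had a median of 5.73 and fibroblast markers one of −2.12, so its values between depots mix cell types. With 996 and 727 of 7197 genes at least 2-fold apart, KRT18 (0 against 2140.4 CPM) was at least 165-fold higher and the haptoglobin gene HP (0 against 948 CPM) at least 73.0-fold higher in the omental library. TM4SF1 stood at 4.33 against 1441 CPM, with 1 subcutaneous UMI and a ratio between 59.7 and 13158. MFAP5 at 718 against 5.90 CPM (122-fold, 73.8 to 214), CD36 at 398 against 1.39 CPM (287-fold, 108 to 1075) and FABP4 at 995 against 19.4 CPM (51.2-fold, 38.1 to 69.9) were higher in the subcutaneous library.

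Each of the following lists lay on the same side of 0 in all 4 clusters. Subcutaneous patterning factors such as IRX2 had medians of −2.54, −2.69, −2.35 and −2.67 in clusters 0, 1, 3 and 5, and visceral factors such as TCF21 medians of 1.80, 1.94, 1.38 and 2.25. Retinoid genes such as ALDH1A1 had medians of 1.21, 1.54, 0.91 and 1.55, and heat shock genes such as HSPH1 medians of 0.46, 0.74, 0.79 and 0.37. NF-κB genes such as ICAM1 had medians of −0.85, −0.70, −0.97 and −0.17, and cytokine genes such as CXCL3 medians of −0.29, −1.01, −0.89 and −0.11. In cluster 5 both lay inside the central 95% of random lists, at percentiles 28.7 and 35.6. The cytokine members were split in clusters 0, 1, 3 and 5, with 6, 8, 4 and 7 above and 7, 9, 9 and 9 below 0. The glucocorticoid response list, with TXNIP and GLUL, had medians of 0.42, 0.43, 0.11 and 0.53, and in cluster 3 the percentile was 87.3, with 5 genes higher and 7 lower in the omental library by 2-fold.

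A further comparison asks in which fibroblast clusters the glucocorticoid genes are most abundant. FKBP5 and ZBTB16 were highest in cluster 0 of both libraries, TSC22D3 and PER1 in cluster 3, and the cytokine-rich cluster 1 held more NFKBIA than clusters 0 and 3. The counting interval of the highest cluster overlapped that of another for FKBP5 and ZBTB16 in the subcutaneous library and for PER1 in both. FKBP5 stood in clusters 0, 1, 3 and 5 at 92.1, 82.2, 61.9 and 30.3 CPM in the subcutaneous library and at 209, 119, 102 and 156 CPM in the omental library. ZBTB16 stood at 227, 207, 216 and 90.9 CPM, and at 339.7, 284, 234 and 196 CPM. TSC22D3 reached 737 CPM in cluster 3 of the subcutaneous and 783 CPM in that of the omental library, and PER1 63.5 and 84.6 CPM. The cortisol-activating enzyme HSD11B1 stood at 14.9, 27.0, 36.8 and 69.2 CPM in the subcutaneous and at 25.3, 32.4, 84.1 and 13.2 CPM in the omental library, so that cluster 5 was highest in the former and lowest in the latter. Its subcutaneous value in cluster 5 came from 16 UMIs (39.6 to 112), overlapping that of cluster 3 (27.1 to 49.0), and cluster 5 holds different cells in the 2 libraries. NR3C1 stood at 99.4, 71.9, 99.5 and 90.9 CPM, and at 134, 84.5, 114 and 61.4 CPM. Against the mean of the other clusters, the response list had medians of −0.14, 0.22, −0.14 and −0.02 in the subcutaneous and −0.12, 0.12, −0.40 and −0.08 in the omental library, with cluster 1 on top in both. With FKBP5, TSC22D3, ZBTB16, KLF9 and PER1 alone the order changed, to cluster 3 on top in the subcutaneous (0.30, against 0.21 in cluster 1) and cluster 0 in the omental library (0.30, against 0.06). NFKBIA stood at 1359, 2982, 2005 and 3535 CPM, and at 573, 1445, 883 and 1542 CPM. For the median of the whole response list, the gap from the highest to the lowest cluster was a log2 fold of 0.36 and 0.53, less than 2-fold in each library.

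**Figure D2:**
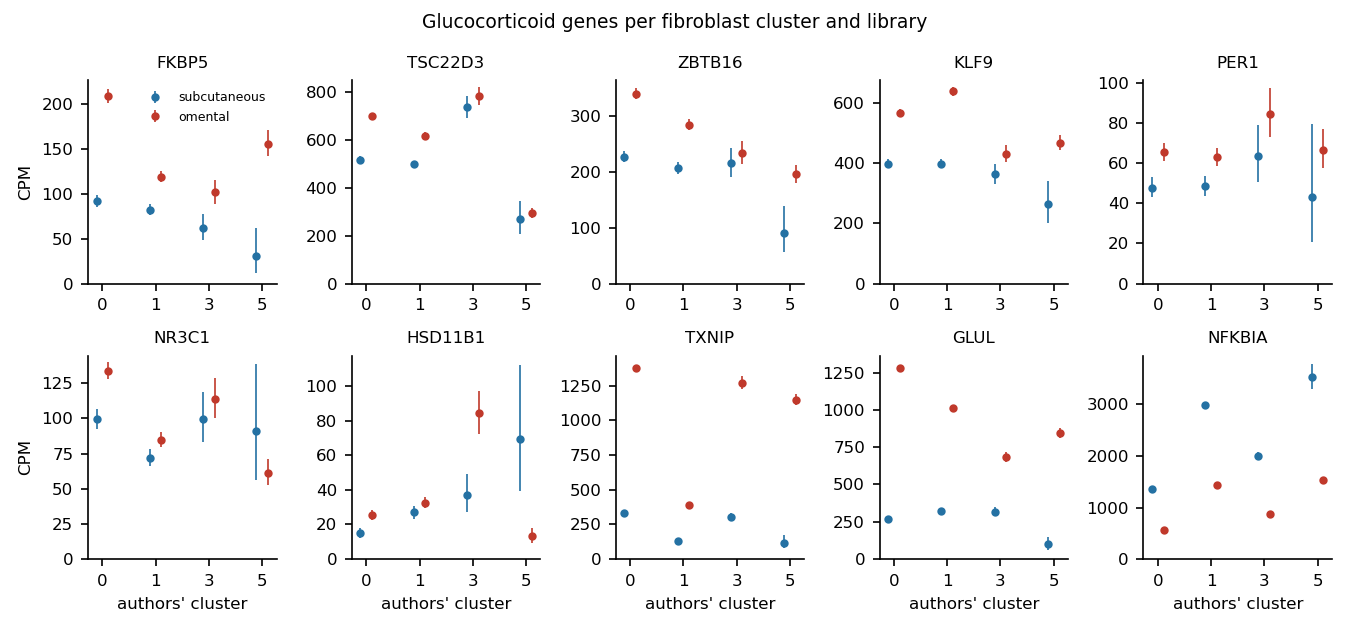
Each panel gives 1 glucocorticoid gene in CPM (axis from 0) for the authors' clusters 0, 1, 3 and 5, in the subcutaneous and the omental library, with exact 95% Poisson intervals. FKBP5 in cluster 0 stands at 92.1 CPM in the subcutaneous and at 209 CPM in the omental library.

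The cell classes of all 18783 cells were then compared for their shares, with the reservation that sorting on CD45 sets the balance of immune and other cells. The omental library held many cells like mesothelium, with ITLN1, MSLN and UPK3B, and the subcutaneous library 1. Fibroblasts made up 60.1% (58.4 to 61.9) of subcutaneous and 34.97% (34.2 to 35.7) of omental cells, and mesothelial-like cells 0.0322% (0.000816 to 0.179) against 14.3% (13.7 to 14.8). T cell-like cells made up 11.6% against 18.8%, macrophage- and monocyte-like cells 1.19% against 8.02%, NK cell-like cells 8.28% against 6.34%, and B and plasma cell-like cells 1.26% against 3.09%. Pericyte- and smooth muscle-like cells made up 2.67% against 3.97%, endothelial-like cells 2.16% against 2.53% and lymphatic endothelial-like cells 0.0645% against 0.804%. Cluster 8, unnamed because macrophage and dendritic markers such as C1QC and CD1C tied, held 10.5% against 3.30%, and cluster 11, unnamed and with TPSAB1 among its leading genes, 1.97% against 2.61%. A cluster of 148 fibroblast-like cells led by GREM1 and FMO2 was found in the omental library alone, 0.944%, where 0 of 3103 subcutaneous cells allow up to 0.0967% by the floor of 3 counts. Other cells in fibroblast clusters were 0.193% against 0.389%. Among the 2025 and 9074 cells left without the immune classes and without the unnamed clusters 8 and 11, which were set aside with them, fibroblasts were 92.1% against 60.4% and mesothelial-like cells 0.0494% against 24.7%.

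**Figure D3:**
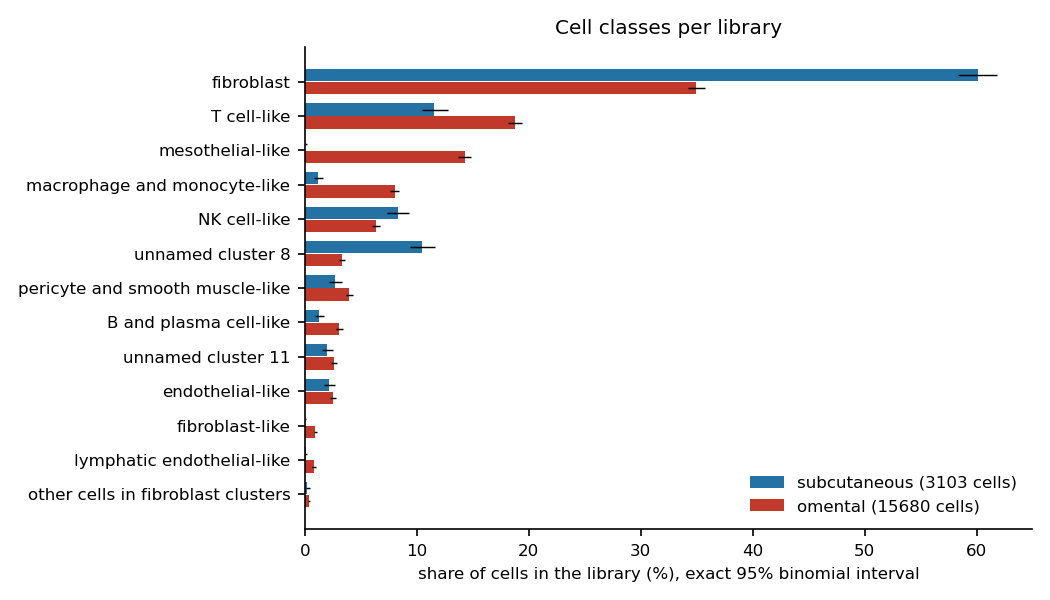
Bars give the share of cells (%) of each cell class in the subcutaneous (3103 cells) and the omental library (15680 cells), from 0, with exact 95% binomial intervals. Fibroblasts make up 60.1% and 34.97%, and mesothelial-like cells 0.0322% and 14.3%.

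Within the other classes, vessel wall cells differed in inflammatory genes. Subcutaneous endothelial-like and pericyte-like cells held more of the neutrophil chemokine CXCL3, and the former more of CXCL1 and of the lipid droplet gene G0S2. Omental NK-like and T-like cells held more IFIT2, an interferon-induced gene. Endothelial-like cells had 878 of 7592 measured genes at least 2-fold higher in the omental and 207 in the subcutaneous library (687 and 199 of these with a counting interval that excludes 1). CXCL3 stood there at 1261 against 38.9 CPM (32.4-fold, 24.6 to 43.4), G0S2 at 2159.7 against 89.8 CPM (24.0-fold, 19.99 to 29.1) and CXCL1 at 244 against 12.1 CPM (20.2-fold, 12.1 to 35.7). On the omental side the chemokine CCL5 (0 against 175 CPM) was at least 21.0-fold higher, and PTGDS at 2.77 against 211 CPM (76.2-fold, 13.6 to 3018) and CD69 at 2.77 against 208 CPM (75.0-fold, 13.4 to 2970.2) each had 1 subcutaneous UMI. Pericyte-like cells had 273 and 144 of 6972 genes, with CXCL3 at 147 against 10.9 CPM (13.5-fold, 9.33 to 19.8), the matrix gene POSTN at 169 against 15.01 CPM (11.3-fold, 8.13 to 15.7) and the urokinase PLAU at 127 against 12.3 CPM (10.3-fold, 7.11 to 14.98) higher in the subcutaneous library. On the omental side PTGDS stood at 1.69 against 143 CPM (84.5-fold, 15.1 to 3344), KRT18 at 3.38 against 237 CPM (70.2-fold, 19.4 to 580.1) and ITLN1 at 0 against 289 CPM (at least 57.0-fold higher). ITLN1 and KRT18 are mesothelial transcripts that were also found in omental lymphoid cells, ITLN1 at 37.5 CPM. Transcripts of other cell types were higher in the omental library in both classes. In endothelial-like cells the fibroblast markers had a median log2 fold of 2.09 (10 of 12 by 2-fold), T cell markers 2.73 and NK cell markers 2.86 (5 of 5 each), so CCL5, CD69 and PTGDS were not separated from RNA of other cells. In pericyte-like cells the fibroblast markers had a median of 0.91 and the mesothelial markers 3.78.

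Among immune classes, NK-like cells had 102 and 43 of 7292 genes at least 2-fold higher in the omental and the subcutaneous library. IFIT2 stood at 20.6 against 432 CPM (21.0-fold, 13.4 to 34.998), IFIT3 at 16.2 against 137 CPM (8.43-fold, 5.05 to 15.2) and the chaperone HSPA6 at 77.9 against 391.97 CPM (5.03-fold, 3.96 to 6.47), and on the subcutaneous side the collagen gene COL1A1, a fibroblast transcript, at 73.6 against 10.8 CPM (6.83-fold, 4.44 to 10.7), LMNA at 1150.2 against 265 CPM (4.33-fold, 3.95 to 4.75) and MT1F at 74.7 against 18.3 CPM (4.08-fold, 2.83 to 5.92). T-like cells had 132 and 52 of 6441, with IFIT2 at 7.44 against 54.2 CPM (7.30-fold, 4.05 to 14.7), IGFBP7 at 9.46 against 53.5 CPM (5.65-fold, 3.34 to 10.4) and CCL3L1 at 22.3 against 103 CPM (4.61-fold, 3.26 to 6.73), and on the subcutaneous side CGA at 72.3 against 0.382 CPM (189-fold, 71.8 to 708), MT1G at 535 against 84.5 CPM (6.33-fold, 5.75 to 6.98) and MT1E at 1978 against 453 CPM (4.36-fold, 4.16 to 4.57). They came from 2 clusters, with 273 and 86 subcutaneous but 1559 and 1385 omental cells. In T-like cells fibroblast markers had a median of 0.49 (8 above and 2 below 0) and mesothelial markers 2.91 (3 of 3 by 2-fold). B and plasma cell markers stood at 3.25 (3 of 4 by 2-fold). IGFBP7, which fibroblasts carry at higher levels, was therefore not separated from RNA of other cells. Macrophage- and monocyte-like cells, 37 of them subcutaneous, had 513 and 227 of 6394 genes, 262 and 191 of these with an interval that excludes 1. They pooled cluster 9, with 26 subcutaneous and 726 omental cells, cluster 16, with 11 and 336, and cluster 17, with 0 and 195, so differences within this class mix clusters. The cytokine TNF stood there at 455 against 88.5 CPM (5.13-fold, 4.17 to 6.27), the iron hormone HAMP at 60.9 against 4.22 CPM (14.4-fold, 7.32 to 27.1) and CXCL5 at 52.8 against 6.76 CPM (7.81-fold, 3.92 to 14.5), and on the omental side IL32 (0 against 92.5 CPM, at least 7.60-fold higher), KLRB1 (0 against 89.1 CPM, at least 7.32-fold higher) and CD69 at 16.2 against 347 CPM (21.4-fold, 8.33 to 78.4). IL32, KLRB1 and CD69 are lymphocyte transcripts, and T cell markers as a list had a median of 2.66 in this class (9 of 10 by 2-fold). Cluster 8 had 160 and 94 of 6435 genes, with the chemokines CCL17 at 213 against 7.71 CPM (27.6-fold, 19.5 to 40.4) and CCL22 at 133 against 8.88 CPM (15.002-fold, 10.7 to 21.5) and the lipid carrier FABP4 at 2565 against 51.2 CPM (50.1-fold, 43.8 to 57.6) higher in the subcutaneous library. FN1 at 2.90 against 148 CPM (51.1-fold, 26.8 to 112), CD3E (0 against 52.8 CPM, at least 54.6-fold higher) and KLRB1 at 3.55 against 78.5 CPM (22.1-fold, 12.2 to 44.8) were higher in the omental library, along with T cell markers (median 2.14, 9 of 9 above 0) and fibroblast markers (1.12, 6 of 10 by 2-fold). B- and plasma-like cells pooled cluster 15 of B cells, with 13 subcutaneous and 344 omental cells, and cluster 18 of plasma cells, with 26 and 140, so differences within this class mix both types. They had 476 and 616 of 6425 genes, 272 and 503 of these with an interval that excludes 1. CCL3 stood at 4.11 against 300.3 CPM (73.1-fold, 13.1 to 2890.1, from 1 subcutaneous UMI), KRT18 (0 against 167 CPM) was at least 13.5-fold higher and MT1G (0 against 121 CPM) at least 9.83-fold higher, and on the subcutaneous side KRT5 at 485 against 26.4 CPM (18.4-fold, 13.7 to 24.7), NPPC at 98.6 against 7.92 CPM (12.4-fold, 6.77 to 22.9) and HIST1H2BG at 193 against 25.1 CPM (7.70-fold, 5.23 to 11.2). In B- and plasma-like cells T cell markers had a median of 2.71 (7 of 9 by 2-fold), mesothelial markers 3.51 (5 of 5) and fibroblast markers 0.82 (10 of 10 above 0). The genes on the omental side of this class were therefore not separated from RNA of other cells. Cluster 11 had 914 and 947 of 6995 genes, but only 116 and 236 of these with an interval that excludes 1. CACYBP (0 against 82.8 CPM), KRT18 (0 against 78.8 CPM) and ITLN1 (0 against 76.9 CPM) had no subcutaneous UMI there and were at least 2.19-, 2.08- and 2.03-fold higher in the omental library against the floor, with counting intervals that begin at 1.70, 1.62 and 1.57. On the subcutaneous side NTRK2 (50.4 CPM from 4 UMIs, against 0) was at least 8.53-fold higher against the floor, with an interval that begins at 4.22. HAUS6 stood at 126 against 7.88 CPM (16.0-fold, 4.61 to 69.9) and PARG at 88.3 against 5.91 CPM (14.9-fold, 3.41 to 89.5).

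The lists placed fibroblasts beside their neighbours. NF-κB genes such as ICAM1 and TNFAIP3 had medians below 0 in pericyte-like cells (−1.20, 9 of 17 lower in the omental library by 2-fold), endothelial-like cells (−1.07, 10 of 17), cluster 8 (−0.66, 4 of 18) and macrophage-like cells (−0.59, 4 of 17). The medians were smaller in NK-like cells (−0.26, 0 of 16), T-like cells (−0.24, 1 of 16) and cluster 11 (−0.15, percentile 37.4), and B- and plasma-like cells, at 0.20, had 7 members above and 7 below 0. Cytokine genes such as CXCL3 had medians of −2.37 in endothelial-like cells, −1.60 in pericyte-like cells, −0.40 in macrophage-like cells and −0.39 in cluster 8. They lay above 0 in T-like (0.35), B- and plasma-like (0.22) and NK-like cells (0.18) and in cluster 11 (0.56). The glucocorticoid response list, with TXNIP and GLUL, had medians of 0.44 in B- and plasma-like, 0.39 in endothelial-like, 0.28 in pericyte-like, 0.11 in macrophage-like, 0.10 in T-like and 0.04 in NK-like cells, the last 3 inside the central 95% of random lists (percentiles 86.3, 89.0 and 52.7). Cluster 8 at 0.02 (percentile 35.6) and cluster 11 at 0.08 (percentile 86.3) lay inside it too. In pericyte-like cells the patterning lists also differed, with a median of −1.18 for subcutaneous factors such as TBX15 and IRX1 (5 of 8 lower by 2-fold) and of 1.70 for visceral factors such as TCF21 (5 of 7 higher by 2-fold). The interferon response list had medians of 0.37 in cluster 8 (percentile 99.5), 0.27 in NK-like (98.6), 0.17 in B- and plasma-like (96.5) and 0.16 in T-like cells (82.0), with 3 of 18 members, IFIT2 among them, at least 2-fold higher in T-like cells. It stood at 0.25 in endothelial-like cells (82.6), 0.07 in cluster 11 (69.5), 0.03 in macrophage-like cells (32.1) and −0.02 in pericyte-like cells (28.9).

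**Figure D4:**
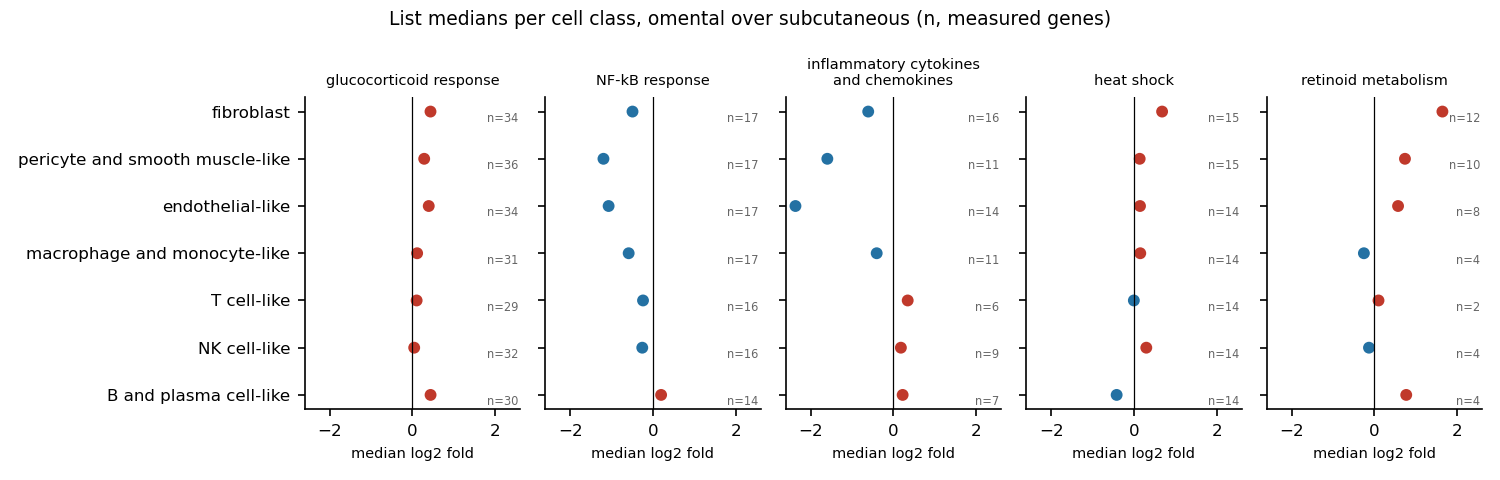
Each panel gives 1 gene list, each dot the median log2 fold, omental over subcutaneous, of the measured genes (n) in 1 cell class. The NF-κB median lies below 0 in 6 of 7 classes, with pericyte- and smooth muscle-like cells at −1.20 and B- and plasma-like cells at 0.20.

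The last comparison asks which cell classes carry the glucocorticoid genes. TSC22D3, an anti-inflammatory leucine zipper gene, was most abundant in lymphoid cells, whereas the cortisol-activating enzyme HSD11B1 was higher in fibroblasts than in the immune or vascular classes. TSC22D3 stood at 3475 and 2343 CPM in NK-like cells of the subcutaneous and the omental library, at 3077 and 3023 CPM in T-like cells and at 522 and 636 CPM in fibroblasts. HSD11B1 stood at 22.7 and 31.2 CPM in fibroblasts, at 29.4 CPM in other cells of fibroblast clusters and 17.4 CPM in fibroblast-like cells of the omental library, and at 4.06 and 0.362 CPM in macrophage-like cells, the former from 1 UMI. NR3C1 reached 333 and 139.9 CPM in B- and plasma-like cells and 169 and 126 CPM in T-like cells, against 87.1 and 107 CPM in fibroblasts. Against the mean of the other classes, the response list had its highest median in fibroblasts, 0.55 in the subcutaneous library (37 genes, percentile 99.4) and 0.66 in the omental library (36 genes, percentile 100.0). Pericyte-like cells stood at 0.32 and 0.23, below other cells in fibroblast clusters (0.42) and fibroblast-like cells (0.31) in the omental library, and B- and plasma-like cells were lowest at −1.85 and −1.74. With FKBP5, TSC22D3, ZBTB16, KLF9 and PER1 alone, fibroblasts lay below the mean of the other classes, at −0.72 and −0.0841. The list of the receptor and cortisol metabolism lay at 0.08 and 0.06 in fibroblasts.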

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

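No paired analysis was possible because the cells carry no donor. For the same reason the planned fits across donors, those leaving out a donor and the permutations between depots were not run. The alternative named for log values as deposited used log values of the scaled counts, since the deposited values are counts. Requiring at least 50 cells would leave out cluster 5 and the macrophage-like and B- and plasma-like classes, which have fewer subcutaneous cells. The counts over clusters and classes were not recomputed without them. For all fibroblasts together this rule changes nothing, so its values equal the reported ones by construction and are included in the totals below. The mean of per-cell CPM, leaving out the authors' cluster 5, leaving out cells in mesothelial-like clusters, and equal weights for the clusters were chosen after the data were seen. Over 63 results and 580 alternative values, 334 stayed close to the reported value, 238 moved and 8 are set out below as changes of sign. Lists inside the tails of the random lists or without a percentile counted too, 17 alternative values had the opposite sign. Of 309 alternative values for the 22 lists in the outer tails of the random lists, 303 kept their sign.

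Of the fibroblast genes, 181 were at least 2-fold higher in the omental and 105 in the subcutaneous library with 20 CPM added before the logarithm, which by construction pulls folds of low genes toward 0. With a mean of at least 50 CPM required, fewer genes were measured and 135 and 83 remained at that size. By the mean of log values per cell 195 were higher in the omental library, and the cause was not tested. This average depends by construction on the UMIs per cell, whose median was 8739.5 in subcutaneous and 5105 in omental fibroblasts. The part of this difference in depth was not separated here or in the other shifts by the mean of log values. Within the authors' clusters, 2165 pairs of gene and cluster were at least 2-fold higher in the omental and 1307 in the subcutaneous library. These counts became 1033 and 699 with 20 CPM added and 655 and 559 with at least 50 CPM, and 3909 pairs were higher in the omental library with no filter. Over the 6 named classes other than fibroblasts, clusters 8 and 11 left out, 2374 and 1289 pairs became 710 and 450 with 20 CPM added and 381 and 449 with at least 50 CPM, and 5620 were higher in the omental library with no filter.

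The glucocorticoid response list, with a median of 0.44, stayed above 0 throughout: 0.41 with no filter, 0.38 after centring on the median gene, 0.27 by the mean of log values, 0.48 without cells holding at least 3 mesothelial markers, 0.49 by the mean of per-cell CPM, 0.48 without cluster 5 and 0.47 without cells in mesothelial-like clusters. The NF-κB list, at −0.49, stayed below 0, at −0.35 with 20 CPM added, −1.07 with at least 50 CPM and −0.72 by the mean of log values. The mesothelial list, at 3.93, stood at 6.16 and 2.24 with 1 and 20 CPM added, 2.56 with no filter, 4.73 with at least 50 CPM, 1.95 by the mean of log values, 3.82 with equal numbers of cells and 4.06 with equal cluster weights. It stood at 3.64 by the mean of per-cell CPM, and at 2.70, 2.89 and 2.44 without cells holding 3 markers, cluster 5, or cells in mesothelial-like clusters, which hold these transcripts. Except where cells or low genes were removed or the added CPM changed, the cause was not tested.

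The collagen and core matrix list changed sign, from 0.18 to −0.0236 with at least 50 CPM, −0.11 by the mean of log values and −0.15 with equal cluster weights. The TGF-β list changed from 0.40 to −0.0370 with equal weights, the immediate early list from 0.12 to −0.0929 by the mean of log values, and the macrophage list from −0.48 to 0.19 with no filter. Equal weights raise the shares of clusters 3 and 5. In clusters 0, 1, 3 and 5 the collagen list stood at −0.20, 0.23, −0.39 and −1.34. The TGF-β list stood there at 0.33, 0.79, −0.07 and −0.52. Lists inside the tails changed sign as well. The DPP4 and PI16 list went from 0.10 to −0.16 by the mean of log values, against 0.25 with equal weights, and matrix remodelling enzymes from −0.16 to 0.40 with at least 50 CPM. Interferon response genes went from 0.07 to −0.0593 by quantile normalization and −0.13 by the mean of log values. Of the lists with too few measured members for a percentile, endothelial and T cell genes, with 1 each, went from −2.26 and −0.99 to 0.14 and 0.28 with no filter. Cell cycle genes, with 2 measured and near 0, changed sign in 3 alternatives. Changing the filter alters by construction which members are measured, not their folds. For the other alternatives the cause was not tested in any of these lists.

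Other medians kept their sign but changed in size. Visceral patterning factors, at 1.83, stood at 4.42 with at least 50 CPM, 1.24 with no filter and 1.03 with 20 CPM added. Subcutaneous patterning factors, at −2.75, stood at −4.73 and −1.59 with 1 and 20 CPM added and −1.70 with no filter. The synovial lining list, at 0.46, stood at 0.08 by the mean of log values, and the receptor and cortisol list, at 0.33, at 0.17 by it and 0.20 with at least 50 CPM. For the shifts by the mean of log values the cause was not tested.

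Fibroblasts against other classes had a glucocorticoid response median of 0.55 in the subcutaneous library, which was 0.37 with 20 CPM added and −0.72 with FKBP5, TSC22D3, ZBTB16, KLF9 and PER1 alone. In the omental library the 0.66 became −0.0841 with these 5 genes, of which TSC22D3 is most abundant in lymphoid cells. The gap between the highest and the lowest cluster in the subcutaneous library, 0.36, became 1.41 with these 5 genes, with cluster 3 rather than 1 on top. This gap was set by cluster 5, with 20 subcutaneous fibroblasts, at −1.11, whereas clusters 0, 1 and 3 lay close together at 0.22, 0.21 and 0.30. Why cluster 5 lay lower was not tested. In the omental library cluster 0 was on top with these 5 genes, with a gap of 0.52. The omental share of fibroblasts was lower by a difference of −31.7 percentage points, and that of mesothelial-like cells higher by 24.6, when the immune classes and the unnamed clusters 8 and 11 were left out, since these cells leave the denominator. Depth limits groups with few subcutaneous cells or UMIs, such as the 37 macrophage-like and 39 B- and plasma-like cells, the 20 fibroblasts of cluster 5 and cluster 11 with 79287 UMIs.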

Other observations

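The genes of the first 3 paragraphs were chosen after their values were seen, and the 6 tests further on were fixed before their results were seen. Pericyte-like cells of the omental library carried patterning genes of both depots. HOXC9, a homeobox gene of the trunk, stood at 14.3 CPM (10.9 to 18.4) in omental pericyte-like cells, from 59 UMIs, but at 0.199 CPM (0.0730 to 0.433) in omental fibroblasts. In the subcutaneous library it stood at 20.3 CPM in pericyte-like cells and 39.4 CPM in fibroblasts. IRX2 stood at 16.7 CPM (13.0 to 21.1) in omental pericyte-like cells, from 69 UMIs, against 0.166 CPM in omental fibroblasts and 0.145 CPM in omental mesothelial-like cells. TCF21, a regulator of visceral mesenchyme, stood at 105 CPM (94.9 to 115) in the same omental pericyte-like cells, with no UMI in the subcutaneous ones, whose interval reaches 6.24 CPM. In omental T-like cells TCF21 stood at 2.58 CPM, and in omental mesothelial-like cells at 144 CPM. Fibroblast and mesothelial markers were also higher in omental pericyte-like cells, so RNA of those cells was not excluded as a part of this TCF21 level.

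The cytokine IL6 and the monocyte chemokine CCL2 showed the depots apart in vessel wall cells more than in fibroblasts. In endothelial-like cells IL6 stood at 4300.1 CPM (4089 to 4520) in the subcutaneous and 616 CPM (577 to 657) in the omental library, and CCL2 at 4164 CPM (3956 to 4380) and 440.5 CPM (407 to 475). In pericyte-like cells IL6 stood at 1477 and 304 CPM, and CCL2 at 3596 and 1185 CPM. Omental mesothelial-like cells held CCL2 at 1845 CPM and IL6 at 91.0 CPM. Among NK-like cells the interferon-induced gene ISG15 stood at 141 CPM (118 to 167) in the subcutaneous and 272 CPM (254 to 291) in the omental library, on the side of IFIT2 and IFIT3, whereas in fibroblasts ISG15 stood at 49.1 and 24.8 CPM.

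TXNIP, the glucocorticoid response gene with the largest log2 fold in fibroblasts after adding 5 CPM, was also higher in other omental cells, at 1026 and 2437 CPM in T-like, 466 and 2094 CPM in endothelial-like and 195 and 393 CPM in pericyte-like cells. Omental endothelial-like cells also held more T cell markers (median log2 fold 2.73) and fibroblast markers (2.09), and pericyte-like cells more fibroblast markers (0.91). The TXNIP rise in these vessel wall classes was therefore not separated from RNA of other cells. FKBP5 was higher in omental macrophage-like cells, at 138 CPM (95.6 to 193) and 333 CPM (320.4 to 345), and in omental pericyte-like cells, at 72.8 and 143 CPM. Macrophage-like cells pooled several clusters, and T cell markers were higher in the omental ones (2.66). Neither FKBP5 difference was separated from RNA of other cells, nor that of macrophage-like cells from the mix of clusters. GLUL, by contrast, was 3.71-fold higher in omental fibroblasts but lay at 189 and 95.04 CPM in B- and plasma-like and at 799 and 621 CPM in macrophage-like cells. The B- and plasma-like class held mostly plasma cells in the subcutaneous and mostly B cells in the omental library. Its GLUL values therefore mix cell types, and those of macrophage-like cells mix clusters. The clustering of all cells separated fibroblasts by depot. Cluster 2, led by CTHRC1 and XG, held 1851 subcutaneous and 11 omental cells, and cluster 6, led by CCL11 and GREM1, 0 and 1171.

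Mesothelial markers, led by KRT18, KRT8 and KRT19, were higher in omental fibroblasts, with a list median of 3.93. Free RNA of lysed mesothelial cells would give fibroblasts and lymphoid cells alike levels, but the median marker was 5.23-fold (4.93 to 5.87) higher in omental fibroblasts than in lymphoid cells, which argues against it as the main source. Mesothelial cells counted among the fibroblasts are a candidate source, since without 190 omental fibroblasts in mesothelial-like clusters this ratio was 0.919 (0.820 to 1.05) and ITLN1, at 5892 CPM in mesothelial-like cells, stood at 21.2 CPM. That test is partly circular because the clusters were named by these markers, and the CD45 sort would not remove mesothelial cells. Free RNA would also give a ratio as low as 0.919, so it stays open as the source of most markers in the remaining omental fibroblasts. In these remaining fibroblasts WT1 at 73.1 CPM and SLPI at 68.8 CPM stayed 30.3-fold and 7.86-fold above lymphoid cells. For these genes a depot difference of the fibroblasts themselves stays open and was not tested.

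NF-κB genes such as ICAM1, CXCL2 and TNFAIP3 were lower in omental fibroblasts, with a list median of −0.49. The median was −0.59 (−0.73 to −0.45) with equal cluster weights, but these raise the share of cluster 5, which sets different cells side by side. Within clusters 0, 1 and 3 the medians were −0.85, −0.70 and −0.97, which argues against the mix of these 3 clusters as the source. The clustering of all cells parted the depots within these clusters as well. A finer difference in cell makeup therefore stays open and was not tested. A difference in handling between the libraries may have set these genes, since the median over 6 other cell classes was −0.42 (−0.53 to −0.31), with 5 of 6 on the same side and B- and plasma-like cells at 0.20 as the exception. That class held mostly plasma cells in the subcutaneous and mostly B cells in the omental library, so its value mixes cell types. A difference between the depots that acts on many cell types would look the same, and it stays open and was not tested.

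Glucocorticoid response genes such as TXNIP, GLUL and FKBP5 were higher in omental fibroblasts, with a list median of 0.44. The median was 0.43 (0.29 to 0.46) with equal cluster weights, which again raise the share of the mixed cluster 5. Within clusters 0 and 1 the medians were 0.42 and 0.43, which argues against the mix of these clusters as the source. In cluster 3 the median was 0.11, inside the central 95% of random lists. A finer difference in cell makeup within the clusters stays open and was not tested. Over the 6 other cell classes the median was 0.20 (0.15 to 0.30), with 6 of 6 above 0, the highest being the mixed B and plasma class at 0.44, and its interval spans 0.22, the level fixed as the mark of a difference in handling. A difference in handling and a difference between the depots therefore cannot be told apart for this list, and exposure of the donors to glucocorticoids was not tested. The medians of macrophage-, T- and NK-like cells lay inside the central 95% of random lists. Fibroblast markers were also higher in omental endothelial-like, pericyte-like (0.91), B- and plasma-like (0.82) and T-like cells (0.49), but not in macrophage-like (−0.19) or NK-like cells (−0.14). Fibroblasts carried the response list at the highest level, so the class medians were not separated from RNA of fibroblasts.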
